A study of Rattus norvegicus with 13 samples.

How the data were processed

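The series compared the brains of male Fischer F344 rats, an inbred strain, whose mothers had eaten either a control diet or a diet high in fructose from day 1 of gestation to the end of lactation. Per the labels, the offspring were weaned on day 20 and ate ordinary chow until they were 15 months old, so the offspring's own direct exposure to the maternal diet ended at weaning. RNA of the brain without the cerebellum was isolated with Qiazol and RNeasy columns, and labelled cRNA was prepared from 100 ng of RNA with the Ambion and Affymetrix whole transcript kits. There were 13 arrays, 7 of the maternal control group and 6 of the maternal fructose group, and each array was assigned to its group from the diet named in its labels.

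The deposited table held log2 signals for 29214 probe sets of an Affymetrix rat gene array. A probe set is a group of short probes on the array whose signals are combined to 1 value for a transcript. RMA, which corrects the background, equalises the value distributions and summarises the probes, and R version 3.0.1 are named per the submitters' processing notes. The scanner settings and the annotation build behind the table are not given in the sources used here. The array medians lay close together without being equal, so the values had not been forced to 1 shared distribution over the probe sets analysed. The table came without detection p-values, so how far a dim probe set stood above background is unknown, and the number of arrays limits the precision of every value.

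Genes were assigned to probe sets from the platform annotation. In it, 15310 probe sets had 1 gene symbol, 323 had several and 13581 had none. The Entrez identifiers of 15279 of the probe sets with 1 gene were found in a current gene table for the rat, and 0 symbols needed an update. The 15310 probe sets covered 14506 genes, 527 of them with more than 1 probe set, and no gene was named from a probe set with several. Genome coordinates were not used here.

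The 15633 probe sets with at least 1 gene were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), maternal fructose minus maternal control, without a filter on dim probe sets. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with 0.05 as the threshold. The number of probe sets at an unadjusted p under 0.05 was set beside the 5% that chance gives. The labels do not say which litter a sample came from, nor that each came from a separate animal, so the p-values measure the spread between these samples. Differences are given on the log2 scale with their standard error or 95% interval.

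Lists of genes were tested with camera from limma, a test of whether the genes of a list differ from all other genes, with a preset correlation of 0.01 between the genes of a list and the probe set with the highest mean for each gene. The 31 lists covered metabolism (fructose and polyol metabolism, glycolysis, oxidative phosphorylation, insulin and IGF signalling, cholesterol and fatty acid synthesis, fatty acid oxidation), regulation and stress (glucocorticoid axis, circadian clock, oxidative stress, heat shock, immediate early genes, inflammation, chromatin modifiers), neuronal function and disease (excitatory synapse, amyloid and tau genes, hypothalamic neuropeptides), ribosomal proteins, and markers of cell types, brain regions and neighbouring tissues. Each list was also tested with a correlation estimated from the data, with fry, and with an exact 2-sided permutation test of the list mean per array over all 1716 ways to part the 13 arrays into groups of these sizes. With a preset correlation, camera takes its p-values from degrees of freedom set by the number of genes. With an estimated correlation it uses those left by the arrays, which are far fewer, so p-values rise even at an equal correlation. A list is said to turn direction when the direction given by the test changes. For camera this direction is relative to all other genes, so the mean difference of the list can keep its sign.

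The lists, the limma, camera and fry tests, most other settings and the rule for named genes were fixed before the data were examined. The rule took up to 15 probe sets in each direction among those past the threshold, or, where fewer than 10 passed, the 10 with the smallest unadjusted p in that direction. It added up to 4 members of each list with the smallest unadjusted p, 4 for lists past the threshold and 2 for the others, and 13 genes whatever their value, 12 of which are reported here (Khk, Slc2a5, Insr, Igf1r, Nr3c1, Hsd11b1, Fkbp5, Crh, Bdnf, Ttr, Gfap and Mbp). The other 1 is not reported here.

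The scripts were tested on simulated data. With the residuals of these arrays as noise and known differences added among 15633 probe sets, the test of fructose against control recovered 22.4% of 67 genes at a log2 difference of 0.25, 91.0% of 67 at 0.5 and 98.5% of 66 at 1, with 0 false calls. These residuals had the group means removed, so an unchanged probe set had a difference of 0 and could not be called. The added differences were likewise estimated without error, so these shares leave out the chance error of an estimate. With independent noise the shares were 41.8%, 95.5% and 100%, with 5 false calls. The list test called 0 of 31 lists in independent noise without a difference, and called the insulin and IGF list alone when that list was shifted by 0.2. This simulation did not carry the correlation between genes that the real arrays have. The shift of 0.2 was also larger than the mean difference of any real list, so it does not show how the test behaves at those sizes.

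The other settings fixed in this way were all probe sets of the table, a filter on the 30% dimmest probe sets, renewed quantile normalization, centring on array medians, the replicate number as a block, a covariate for the first component of the residuals, an intensity trend with a robust prior, array weights, the probe set with the largest spread per gene, and each array left out in turn. Cyclic loess, the fit without the pair of arrays with the narrowest value distributions (also with an estimated correlation and an exact permutation test of list means on the same 11 arrays), the fit without the block on the 12 arrays of the block fit, the estimated correlation in the fits with 1 array left out, with the block and on those 12 arrays, and the permutation test of list means were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.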

Results

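Gene expression was measured in the brain, without the cerebellum, of 15 month old male F344 rats born to mothers on a control diet (7 arrays) or on a diet high in fructose during gestation and lactation (6 arrays). Array medians over the 15633 probe sets with a gene ran from 7.99 to 8.07 on the log2 scale. Correlations between pairs of arrays ran from 0.9852 to 0.9976. The interquartile range was 2.19 in control replicate 1 and 2.15 in control replicate 2, the narrowest of all, and 2.27 to 2.5 in the other 11 arrays.

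The comparison asked whether the maternal diet left a difference in brain gene expression that could be measured in old offspring long after weaning. In the limma fit 0 of 15633 probe sets passed an adjusted p of 0.05, with 348 (2.23%) at an unadjusted p under 0.05 where chance alone gives 781.65. The smallest adjusted p was 0.9998. Of the 348, 208 were higher and 140 lower in the fructose group. The 95% interval of the difference lay within 1.2-fold for 84.63% of the probe sets, within 1.5-fold for 98.98% and within 2-fold for 99.92%, before any allowance for the number of intervals.

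Among genes higher in the fructose group, the smallest unadjusted p was that of Lbh, a transcriptional cofactor of development, with a difference of 0.21 ± 0.05 (SE). Its level was 8.74 ± 0.08 (SD, n = 7) in control and 8.95 ± 0.08 (SD, n = 6) in fructose samples, and another probe set of the gene was 0.14 higher. Sncb, which encodes beta-synuclein, a protein of presynaptic terminals, was at 11.22 ± 0.08 and 11.41 ± 0.08. Calm2, a calmodulin gene of calcium signalling, was 0.17 higher by the probe set with the smallest p and 0.04 higher by its brighter one, and Grem1, a secreted antagonist of bone morphogenetic proteins, was 0.20 higher. The differences of Snapc5, Prp2, Zfp358, Pcdhb12 and the olfactory receptor genes Or6k8 and Or4k51 lay between 0.15 and 0.24. In the other direction, Krt18, a keratin of simple epithelia, was at 6.82 ± 0.12 (SD, n = 7) in control and 6.57 ± 0.08 (SD, n = 6) in fructose samples, a difference of -0.25 ± 0.06 (SE) for the probe set with the smallest p, while its other probe sets differed by -0.10 and -0.03. Synpr, which encodes the synaptic vesicle protein synaptoporin, differed by -0.29 ± 0.08 (SE), and Il1b, the gene of the cytokine interleukin 1 beta, by -0.15 ± 0.05 (SE). Chmp1b, of the ESCRT membrane remodelling machinery, differed by -0.18 and Zmym1 by -0.17. The olfactory receptor genes Or7g21, Or8b1d, Or4f53, Or1e1c and Or5p60d differed by -0.20 to -0.46. For each of these 20 genes, at the probe set with the smallest p, all 6 fructose arrays lay on the same side of the control mean. The genes were picked for a small p, so this is no separate evidence of a difference. The unadjusted p-values from limma began at 0.000555, and none of the 20 passed the adjusted threshold.

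**Figure D1:**
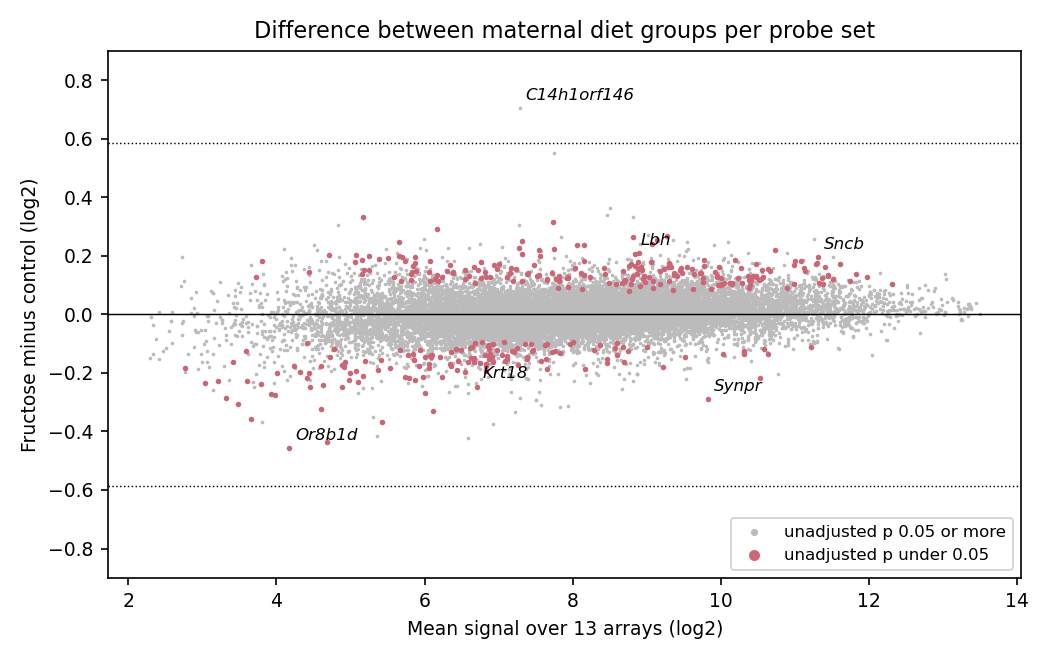
Difference between the fructose and control group (log2) against the mean signal over 13 arrays (log2), 1 point per probe set. Red points are the 348 probe sets at an unadjusted p under 0.05, dotted lines mark a 1.5-fold difference in either direction, and 1 probe set, of C14h1orf146 (0.71), lies beyond them.

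Genes named in advance for their part in fructose handling, hormone action and brain structure did not pass either. Khk, the ketohexokinase that starts fructose breakdown, was at 7.48 ± 0.12 (SD, n = 7) in control and 7.42 ± 0.06 (SD, n = 6) in fructose samples, with a 95% interval of the difference from -0.19 to 0.05 and a difference of -0.07 that was -0.012 without the 2 arrays with the narrowest distributions. The fructose transporter Slc2a5 was at 7.41 in both groups, with an interval from -0.14 to 0.15. The insulin receptor gene Insr was 0.09 higher (interval -0.06 to 0.24), 0.0076 by its other probe set, 0.025 with array weights and 0.021 without the pair of arrays with the narrowest distributions, and Igf1r was 0.04 higher (interval -0.07 to 0.15), 0.0054 with array weights and 0.016 without that pair. Nr3c1, the glucocorticoid receptor, was at 9.86 ± 0.09 (SD, n = 7) and 9.96 ± 0.10 (SD, n = 6), with an interval from -0.01 to 0.22. Its co-chaperone and target Fkbp5 was 0.09 higher (interval -0.15 to 0.33) and 0.0018 without that pair. Hsd11b1, which regenerates active glucocorticoid, Crh and Bdnf differed by 0.04, 0.01 and 0.02. Gfap, of astrocytes, differed by -0.08 (interval -0.58 to 0.42), Mbp, of myelin, by 0.07 (interval -0.25 to 0.39; 0.017 by its other probe set), and Ttr, of the choroid plexus, by -0.26 (interval -0.74 to 0.21; -0.12 without fructose replicate 7, -0.15 without control replicate 3 and -0.45 with array weights), and these 3 varied most between samples of a group. The signs of Slc2a5, Crh, Bdnf, Gfap, Mbp and Hsd11b1 turned in at least 1 other fit. Of the 95 named genes, 36 had a difference over 1.5 times larger or smaller, or turned, without that pair, and 4 to 17 did with 1 array left out, the most without control replicate 1.

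With camera and a preset correlation, 4 of the 31 gene lists passed an adjusted p of 0.05, each by a mean difference under 0.07 on the log2 scale. Astrocyte markers were higher in the fructose group by a mean of 0.062 (adjusted p = 0.0191), with 13 of 17 measured genes higher. The adjusted p = 0.883 with an estimated correlation. Slc1a2 and Slc1a3, the glutamate transporters of astrocytes, were 0.09 and 0.08 higher, S100b 0.15 and the amino acid transporter Slc7a10 0.15. The lowest values of S100b (10.806 and 10.972) and Slc1a3 (11.072 and 11.04) were those of control replicates 1 and 2, the arrays with the narrowest distributions. For Slc1a2 the lowest value was that of control replicate 1 (12.76) and for Slc7a10 that of control replicate 2 (8.62). The next lowest values of these genes were those of other arrays. Insulin and IGF signalling genes were higher by a mean of 0.044 (adjusted p = 0.0191), with 28 of 32 higher, and the adjusted p = 0.754 with an estimated correlation. The kinases Gsk3b, Gsk3a and Akt2 were 0.09, 0.08 and 0.11 higher and Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, 0.07. Genes of the glucocorticoid axis and its targets were higher by a mean of 0.053 (adjusted p = 0.048), with 23 of 26 higher, and the adjusted p = 0.855 with an estimated correlation. They included Nr3c1 (0.10), the phosphatase gene Dusp1 (0.15), the cell cycle inhibitor Cdkn1a (0.11) and the NF-kappaB inhibitor Nfkbia (0.16). Hypothalamic and feeding neuropeptide genes were lower by a mean of -0.062 (adjusted p = 0.0267), with 24 of 32 lower, and the adjusted p = 0.384 with an estimated correlation. That estimate was 0.0111, near the preset 0.01, so the rise does not point to shared variation of these genes. The fewer degrees of freedom used with an estimated correlation raise the p-value even at an equal correlation. The unadjusted p from camera was 0.00259 with the preset and 0.0126 with the estimated correlation. Pmch, Hcrt and Agrp, which encode peptides that promote feeding, differed by -0.14, -0.13 and -0.13 and the melanocortin receptor Mc4r by -0.19. Without the pair of arrays with the narrowest distributions these were -0.093, -0.059, -0.038 and -0.10. Without control replicate 1 alone they were -0.0985, -0.0917, -0.086 and -0.10. Pmch was dim, at a mean signal of 5.78. Trh, also in this list, differed by -0.33, with 9.69 in control replicate 5 and 7.16 or lower in the other control samples. The list still passed without control replicate 5 (adjusted p = 0.0216 from camera with the preset correlation).

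No member of these 4 lists passed over all probe sets tested or adjusted over the list alone, where the counts were 0 and 0 for each list. In the exact permutation test of list means the p-values were 0.449 for astrocyte markers, 0.0769 for insulin and IGF signalling, 0.267 for the glucocorticoid axis and 0.0874 for the neuropeptides, and 0 of the 31 lists passed after adjustment. The number of lists past the threshold was also 0 by fry, with a smallest adjusted p of 0.716. The groups differed in a trend with signal level, from a median difference of -0.02 among the dimmest probe sets (mean signal up to 5.8) to 0.02 among the brightest (10.3 or more). Without the pair of arrays with the narrowest distributions, control replicates 1 and 2, these medians were 0.0152 and 0.0071, so the trend was not seen in the other 11 arrays. None of the 4 lists passed after cyclic loess (adjusted p from 0.074 to 0.0859), after renewed quantile normalization (0.0856 to 0.0973) or without the pair of arrays with the narrowest distributions (0.308 to 0.792), where the mean differences were -0.032 for astrocyte markers, which turned direction, 0.018 for insulin and IGF signalling, 0.033 for the glucocorticoid axis and -0.067 for the neuropeptides. Without that pair 4 other lists passed, all lower in the fructose group: microglia and macrophage markers (mean -0.082, adjusted p = 2.99e-08), ribosomal proteins (-0.046, adjusted p = 9.02e-06), fatty acid oxidation (-0.048, adjusted p = 0.0226) and oxidative stress genes (-0.046, adjusted p = 0.0226). For each of these the adjusted p = 0.721 with an estimated correlation on the same 11 arrays, and the exact permutation p of the list mean was from 0.121 to 0.208 for the last 3. For microglia it was 0.00216, the smallest exact p that the 462 splits of 11 arrays can give, which over 31 lists is adjusted to 0.0671 for a single list, so this test could not have passed that list alone. Leaving out fructose replicate 1 or fructose replicate 7 left 0 lists past the threshold.

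**Figure D2:**
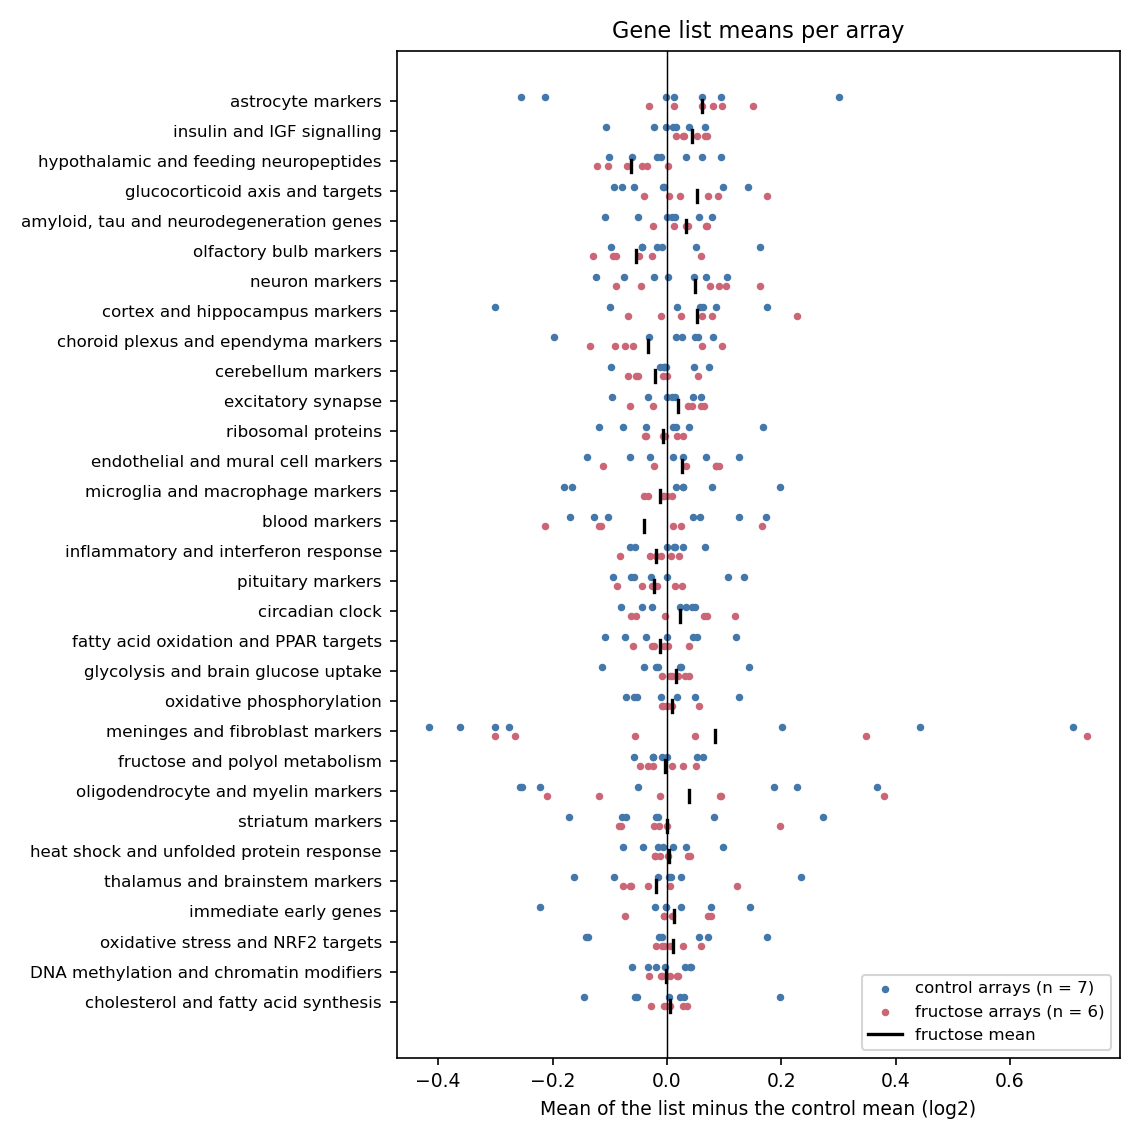
Mean of each gene list per array, as the difference from the control mean (log2). Blue points are the 7 control arrays, red points the 6 fructose arrays and black bars the fructose means, which for all 31 lists lie within the range of the control arrays, and the meninges and fibroblast list spreads over 1.15.

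The other 27 lists did not pass. Among metabolic lists, fructose and polyol metabolism had a mean difference of -0.0026 with 7 of 17 genes higher (adjusted p = 0.617), with Slc2a2 at 0.09 and Hk2 at -0.07. Glycolysis and glucose uptake had a mean difference of 0.016 (17 of 27 higher, adjusted p = 0.466), with Slc2a1 0.13 and Aldoc 0.10 higher. The lowest Aldoc values were those of control replicates 1 and 2, at 12.005 and 12.151. Oxidative phosphorylation had a mean difference of 0.0086 (37 of 58 higher, adjusted p = 0.49), with Ndufa2 at -0.16 and Cox7b at 0.10. Cholesterol and fatty acid synthesis stood at 0.0056 (18 of 32 higher, adjusted p = 0.902), with Insig2 and Elovl6 at 0.09 and 0.08. These last 3 lists turned direction after renewed quantile normalization and after cyclic loess. Fatty acid oxidation stood at -0.012 (14 of 29 higher, adjusted p = 0.466), with Ppargc1a, a coactivator of mitochondrial genes, at 0.11 and Ppara at -0.09.

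Among lists of stress and regulation, the circadian clock stood at 0.022 (13 of 17 higher, adjusted p = 0.293), with the repressors Nr1d2 and Nr1d1 at 0.11 and 0.10. Inflammatory and interferon genes stood at -0.019 (20 of 44 higher, adjusted p = 0.276), where Il1b at -0.15 and Rela at 0.08 had the smallest unadjusted p. Oxidative stress genes stood at 0.010 (19 of 29 higher, adjusted p = 0.774), with Txnrd1 at -0.08 and Sod3 at 0.08, and heat shock genes at 0.0045 (17 of 29 higher, adjusted p = 0.774), with Atf3 at -0.11 and Dnajb9 at 0.09. Both of these turned direction after renewed quantile normalization and cyclic loess. Immediate early genes had a mean of 0.012 and a median of -0.0042 (12 of 25 higher, adjusted p = 0.774), with Fosl2 0.18 higher. Chromatin modifiers had a mean of -0.0015 and a median of 1.45e-05 (17 of 33 higher, adjusted p = 0.809), with Crebbp at 0.06 and Eed at -0.08. Ribosomal protein genes stood at -0.0064 (19 of 51 higher, adjusted p = 0.249), with Rpl5 at 0.10 (-0.0013 and 0.033 by its other probe sets) and Rpl22 at -0.09, and this list passed after renewed quantile normalization (adjusted p = 0.00389) and after cyclic loess (adjusted p = 0.012), lower in the fructose group, with an adjusted p = 0.926 with an estimated correlation on the deposited values.

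Among neuronal lists, neuron markers stood at 0.050 (17 of 21 higher, adjusted p = 0.0749), with Rbfox3, the gene of the nuclear protein NeuN, at 0.15 and Map2 at 0.08. Excitatory synapse genes stood at 0.019 (37 of 45 higher, adjusted p = 0.204), with Vamp2 and Shank1 at 0.10 and 0.12. Amyloid, tau and neurodegeneration genes stood at 0.033 (21 of 26 higher, adjusted p = 0.0521), with the gamma-secretase subunit Psenen 0.09 higher, and passed with arrays centred on their medians (adjusted p = 0.0413) and with an intensity trend and robust prior (adjusted p = 0.0414), with an adjusted p = 0.883 with an estimated correlation on the deposited values. Cortex and hippocampus markers stood at 0.052 (10 of 13 higher, adjusted p = 0.0984), with Emx2 and Cux1 at 0.13 and 0.15. The control mean of Cux1 was lowered by control replicate 1, at 8.715 with the next control sample at 9.028. Olfactory bulb markers stood at -0.055 (8 of 12 lower, adjusted p = 0.0707), with Synpr at -0.29 and Th, of dopamine synthesis, at -0.15. This list passed as lower without the 30% dimmest probe sets (adjusted p = 0.0201), where the glucocorticoid list did not (0.086), and on the deposited values the adjusted p = 0.384 with an estimated correlation. The estimated correlation of the olfactory bulb list was -0.0458, so that value does not point to shared variation of its members. Striatum markers stood at -0.00017 (8 of 16 higher, adjusted p = 0.689), with Isl1 at -0.25 and Rasd2 at 0.25. Thalamus and brainstem markers had a mean of -0.018 and a median of 0.0033 (10 of 19 higher, adjusted p = 0.774), with Hoxa5 at 0.16, and turned direction after both renewed normalizations. Cerebellum markers stood at -0.020 (14 of 20 lower, adjusted p = 0.0996), with Fat2 at -0.10 and Zic4 at 0.13.

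Among glial, vascular and neighbouring tissues, oligodendrocyte and myelin markers stood at 0.038 (12 of 17 higher, adjusted p = 0.617), with Gjb1 at -0.08 and Fa2h at 0.11, and microglia and macrophage markers at -0.013 (12 of 21 lower, adjusted p = 0.267), with Ptprc and Laptm5 at -0.11 and -0.07. With array weights the oligodendrocyte list passed as higher (adjusted p = 0.0154) and the microglia list as lower (adjusted p = 0.0327), and on the unweighted values the adjusted p = 0.926 with an estimated correlation for both. Astrocyte markers did not pass with array weights. Endothelial and mural markers stood at 0.027 (15 of 22 higher, adjusted p = 0.265), with Slc2a1 at 0.13 and Ly6c at -0.16. Ly6c was dim, at a mean signal of 4.64. Choroid plexus and ependyma markers stood at -0.033 (14 of 21 lower, adjusted p = 0.0984), with Drc12 at -0.19 and Cldn2 at -0.21. Pituitary markers stood at -0.022 (8 of 11 lower, adjusted p = 0.276), with Gh1 at -0.13 and Tshb at 0.09, and blood markers at -0.041 (6 of 10 lower, adjusted p = 0.269), with Ahsp at -0.42 and S100a8 at -0.05. Meninges and fibroblast markers stood at 0.085 (14 of 17 higher, adjusted p = 0.588), with Osr1 at -0.12 and Igfbp2 at 0.10. The mean of this list was 7.95 ± 0.45 (SD, n = 7) in control and 8.03 ± 0.40 (SD, n = 6) in fructose samples, the widest spread of any list. Over the 31 lists, 0 members passed over all probe sets tested, and 1 passed adjusted over the list alone, Synpr among the olfactory bulb markers.

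The arrays did not part by maternal diet as whole profiles. The mean distance between arrays of different groups was 0.967 smaller than that between arrays of the same group (-0.967, exact 1-sided permutation p = 0.973). The first principal component held 29.7% of the variance, and its group means did not differ beyond the spread (exact permutation p = 0.852), nor did those of the next 3 components (exact permutation p from 0.528 to 0.989). Control arrays lay a mean distance of 28.1 from each other and fructose arrays 23.7, a difference within that of other groupings (exact 2-sided permutation p = 0.205).

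**Figure D3:**
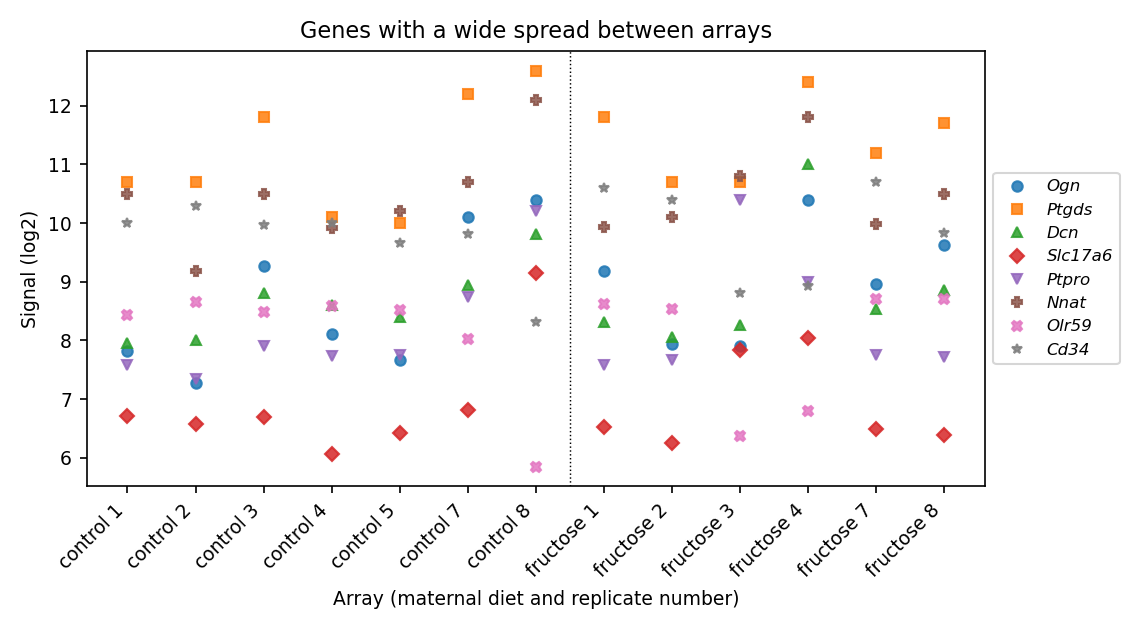
Signal (log2) of 8 genes with a wide spread between arrays, chosen after their values were seen, 1 column per array, with control arrays left and fructose arrays right of the dotted line. Ogn runs from 7.28 to 10.4 and Slc17a6 from 6.07 to 9.15, and high and low arrays lie in both groups.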

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

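The estimated correlation was planned as another setting, while its use to weigh an explanation, the tests with cyclic loess on the first and second pattern, the fit without the pair of arrays with the narrowest distributions, the separate tests of the neuropeptide list, the comparison with random lists of matched signal level and the count of splits with as few probe sets were chosen after the results they address had been seen.

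Between-sample values that stood apart from the rest of their group were sought in 296 groups of values (a gene or list in 1 diet group), and 26 had such a sample where chance, which picks out about 1 in 20 groups, gives 14.8. Of these groups 40 belonged to the 20 genes with the largest SD, chosen for their spread, and held 9 of the 26, while the other 256 groups held 17 where chance gives 12.8. Among list means, oxidative phosphorylation stood at 10.68 in fructose replicate 7 with the next sample at 10.63, choroid plexus and ependyma markers at 6.906 in control replicate 5 with the next at 7.072, and striatum markers at 8.527 in fructose replicate 3 with the next at 8.329. In fructose replicate 8, Slc1a3 was at 11.2, Gsk3b at 11.21, Zic4 at 7, Ahsp at 4.512, Atf3 at 6.617 and Trh at 7.494. In fructose replicate 4, Dnajb9 was at 8.993, Fosl2 at 9.50, Cbln4 at 10.42, Dcn at 10.99 and Cyp11b1 at 5.973, where the nearest other fructose samples were at 8.888, 9.20, 7.996, 8.863 and 8.336. Igf1r was at 9.628 in fructose replicate 3 and Nr1d2 at 9.75 in fructose replicate 1. In control replicate 8, Olr59 was at 5.849, Slc17a6 at 9.149 and Cd34 at 8.317, where the nearest other control samples were at 8.031, 6.819 and 9.663. Mc4r was at 7.403 and Cux1 at 8.715 in control replicate 1, Nkg7 at 9.122 in control replicate 2 with the next at 6.484, Ppara at 7.532 in control replicate 3, and Nr3c1 at 9.681 in control replicate 7. Control replicate 5 had Txnrd1 at 8.405 and Trh, the gene of thyrotropin-releasing hormone, at 9.69, where the other control samples lay at 7.161 or lower.

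The first pattern is the 4 gene lists past the threshold. After cyclic loess 0 of the 4 passed, but the mean differences went from 0.044 to 0.032 for insulin and IGF signalling, from 0.053 to 0.043 for the glucocorticoid axis, from -0.062 to -0.063 for the neuropeptides and from 0.062 to 0.043 for astrocyte markers, with SDs between arrays of a group from 0.022 to 0.189 before and 0.024 to 0.159 after. For the 3 lists other than the neuropeptides, 0 of which passed, the calls ended by a modest shift across the threshold and the trend with signal level may contribute, while the neuropeptide difference did not move toward 0, so its lost call does not decide, and whether the trend is the whole cause stays open: the medians of all 4 lists lay outside the central 95% of 10000 random lists of matched level, but so did 5 of the other 27 lists. Shared variation of list members between samples may contribute for those 3 lists and remains open as a cause. Their estimated correlations were 0.531 (astrocyte markers), 0.144 (glucocorticoid axis) and 0.0808 (insulin and IGF signalling), above the preset 0.01. Their smallest adjusted p from camera was 0.754 once the correlation was estimated, a value that the fewer degrees of freedom also raise. Shared variation is argued against for the neuropeptides, whose estimated correlation of 0.0111 (-0.0115 to 0.0269 with 1 array left out) is near the preset 0.01. As to chance, 83 of the 100 splits of the arrays gave at least 4 lists, and the highest other split gave 16, so chance is not excluded and the arrays hold a structure that lists follow, and by the exact permutation test a difference by maternal diet was not detected in these 4 lists (smallest p = 0.0769).

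The second pattern is that 348 probe sets lay under an unadjusted p of 0.05, fewer than the 781.65 that chance gives on average. Where genes vary together, the count of a single grouping can lie far from this average. Of the 100 splits, 19 gave as few or fewer and 82 as many or more, with a median of 506, a lowest of 201 and a highest of 2664 among the others, so 348 is within what other groupings give, and the split with several times the real count points to a structure of the samples. Uneven spread with signal level may matter and stays open, since the count after cyclic loess was 489 but 717 without the pair of arrays with the narrowest distributions, a fit on fewer samples. Variation along the first component of the residuals may matter: with it as a covariate the count was 597, past the bound set in advance for this explanation, but the component is built to take up residual variance, so the test favours that outcome and cannot decide. For the count of 0 past the adjusted threshold the splits decide nothing, since each of the 100 must give at least 0, and the highest other gave 0.

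The third pattern is the range of 1.15 of the meninges and fibroblast list over the arrays, with Ogn spanning 3.13, Dcn 3.03 and Ptgds 2.60. Uneven spread with signal level is argued against, since the range was 1.16 after cyclic loess. A candidate explanation is a differing amount of meningeal tissue left on the brains: of the 13 measured genes of another list of meningeal genes, written down before the test, 11 correlated over 0.5 with the mean of the first list across the arrays, against 7.74% of all genes. Biological differences in meningeal gene activity between animals were not tested. The list means of the diet groups did not differ beyond the spread between arrays (exact permutation p = 0.721).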

How the results depend on the processing

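Cyclic loess, the fit without the pair of arrays with the narrowest distributions, the fit without a block on 12 arrays, the estimated correlation in fits on part of the arrays or with the block, and the permutation test of list means were chosen after the data had been seen. The count of probe sets past the adjusted threshold was 0 in limma under each of the 24 other settings, with 225 to 871 at an unadjusted p under 0.05 in these fits. These settings are not all separate, since the fit without a block on 12 arrays is that without control replicate 5. Of the 95 named genes 87, and of the 31 lists 13, kept their direction under every setting run. Dim probe sets may carry little signal over background, which is unknown here, and leaving out the 30% dimmest gave 225 probe sets under the unadjusted threshold among 10944 tested.

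The unadjusted count was 871 among all 29214 probe sets, which is a larger number tested, 597 with the first residual component as covariate, 759 with array weights and 717 without the narrowest arrays. With 1 array left out it ran from 248 without fructose replicate 1 to 527 without control replicate 8. Lists past the threshold numbered 1 after renewed quantile normalization and 1 after cyclic loess, the ribosomal list both times (4 without the narrowest arrays, none of them among the first 4), and 0 with an estimated correlation, 0 by fry and 0 by permutation of list means. With 1 array left out the number ran from 0 (without fructose replicate 1, and without fructose replicate 7) to 13 (without control replicate 5), with 10 without control replicate 3, 7 without fructose replicate 3 or 8, and 1 without control replicate 2. In these fits 0 lists passed with an estimated correlation (smallest adjusted p = 0.192). The cause of these shifts was not tested.

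The data do not show that the shared replicate numbers pair the samples. The deviations of same-numbered samples correlated over 0.1 in 1 of 6 pairs, and 0 samples matched their own number best. The labels do not say what the numbers stand for, so a pairing is not excluded. The block fit used the 12 arrays whose number occurs in both groups, so it left out control replicate 5 alone. Without the block, the fit on these arrays is the same as that with control replicate 5 left out. With the replicate block the lists past the threshold numbered 14, and 13 without the block on the same 12 arrays, with unadjusted counts of 310 and 475. Among them were choroid plexus and ependyma markers (adjusted p = 0.00829 with the replicate block and 0.00628 without it), the amyloid and tau list (0.0159 and 0.0134), olfactory bulb markers (0.0229 and 0.0239) and glycolysis (0.0288 and 0.0239). The glucocorticoid list passed neither with the first residual component as covariate nor in either fit on these 12 arrays. With an estimated correlation none of the 31 lists passed in either fit: the adjusted p = 0.594 and 0.599 with an estimated correlation for amyloid and tau, 0.358 and 0.301 for the olfactory bulb and 0.594 and 0.56 for glycolysis. With the replicate block, and without it on the same arrays, the difference of Gfap was 0.065 and that of Mbp -0.00329. Lists that turned direction had adjusted p-values of 0.887 (chromatin modifiers), 0.417 (oligodendrocytes) and 0.54 (meninges) with the replicate block, and of 0.965 (immediate early genes), 0.867 (chromatin modifiers), 0.503 (oligodendrocytes) and 0.455 (meninges) without it on the same arrays.

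Other genes turned direction by small amounts. With array weights Slc2a5 was at -0.00451, Crh at -0.00215 and Bdnf at -0.00233. Without the narrowest arrays Slc2a5 was at -0.0775 and Igfbp2 at -0.00686, and another probe set of Rpl5 was at -0.00133. With 1 array left out, Slc2a5 ran from -0.0459 to 0.0302, Hsd11b1 from -0.00623 to 0.0692, Crh from -0.0554 to 0.0773, Bdnf from -0.0393 to 0.0595, Gfap from -0.186 to 0.065 and Mbp from -0.0112 to 0.146.

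Lists that turned direction did so at these adjusted p-values. After renewed quantile normalization they were 0.929 (glycolysis), 0.22 (oxidative phosphorylation), 0.628 (cholesterol and fatty acid synthesis), 0.799 (oxidative stress), 0.615 (heat shock) and 0.786 (thalamus and brainstem). After cyclic loess they were 0.869, 0.368, 0.671, 0.786, 0.616 and 0.78 for the same lists in this order. Without the narrowest arrays they were 0.56 (glycolysis), 0.308 (oxidative phosphorylation), 0.308 (cholesterol), 0.0226 (oxidative stress, past the threshold), 0.471 (heat shock), 0.941 (amyloid and tau, whose mean difference stayed positive at 0.00119), 0.792 (astrocytes), 0.56 (endothelial and mural), 0.56 (meninges), 0.308 (thalamus and brainstem, whose mean difference stayed negative at -0.012) and 0.471 (pituitary). Without the dimmest probe sets they were 0.724 (cholesterol), 0.889 (oxidative stress) and 0.969 (immediate early genes), with array weights 0.902 (oxidative stress), 0.786 (meninges) and 0.902 (thalamus and brainstem), and by fry 0.923 (chromatin modifiers).

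With 1 array left out, adjusted p-values of lists that turned in at least 1 such fit ran from 0.0239 to 0.946 (glycolysis), 0.0071 to 0.991 (oxidative phosphorylation), 0.0239 to 0.939 (cholesterol), 0.0943 to 0.912 (fatty acid oxidation), 0.132 to 0.91 (oxidative stress), 0.13 to 0.979 (heat shock), 0.185 to 0.965 (immediate early genes), 0.523 to 0.873 (chromatin modifiers), 0.0022 to 0.829 (ribosomal proteins), 0.0387 to 0.924 (oligodendrocytes), 0.00247 to 0.857 (microglia), 0.006 to 0.95 (endothelial and mural), 0.0237 to 0.979 (meninges), 0.131 to 0.897 (striatum) and 0.305 to 0.924 (thalamus and brainstem). The cause of these turns was not tested.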

Other observations

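The genes below were chosen after their values were seen, as were all tests in this part. The median SD of a gene over the 13 arrays was 0.114, and 96 of 14506 genes had an SD over 0.5. Slc17a6, a vesicular glutamate transporter, was at 9.15 in control replicate 8, 8.04 in fructose replicate 4 and 7.83 in fructose replicate 3, and from 6.07 to 6.82 in the other 10 arrays. In the same 3 arrays Ptpro was at 10.2, 9 and 10.4, and Olr59 at 5.85, 6.79 and 6.37, where the others lay at 8.03 or higher. Nnat, an imprinted gene, ran from 9.18 to 12.1, Htr2c, a serotonin receptor, from 7.16 to 10.1 and Nr4a2, a transcription factor of dopamine neurons, from 8.49 to 11.3. For these genes the exact permutation p of the diet groups lay at 0.765 or higher. Cbln4 spanned 3.65, with 10.4 in fructose replicate 4 alone. Trh was at 9.69 in control replicate 5 and at 7.49 or lower in every other array.

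Olfactory receptor genes made up 7 of the 20 genes named by their unadjusted p. Among probe sets with 1 gene, 53 of the 1287 of olfactory, vomeronasal and trace amine receptors (4.12%) lay under an unadjusted p of 0.05, and 283 of the others (2.02%), both under the 5% that chance gives. The receptors were looked at because 7 were among the 20, and those 7 are part of the 53, so the shares are not a test. Their median signal was 5.41 against 8.25 for the others, near the lower end of the range, where the distance from background is unknown.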
